A study of Glycine max with 24 samples.

How the data were processed

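Dual-channel cDNA arrays of immature soybean cotyledons were analysed as 3 families. The side family (14 arrays) compared adaxial with abaxial tissue at days 0, 7, 14, 21 and 28 of culture on 40 mg/L 2,4-D. The time family (8 arrays) compared adaxial tissue between days, in a closed loop of 4 pairs with opposite channel order. The replicate family (2 arrays) compared biological replicates G and F. Per the labels, the arrays were scanned with ScanArray 3000 (14 arrays) or ScanArray Express 1.0 (10 arrays) and quantified with GenePix 3.0. The families were printed in different lots, and the scanner differed between the side arrays and the others. Family, lot and scanner therefore cannot be told apart, and no test of single features compared the families. Where values of different families are set side by side below, as for the noise of day 14, this limit applies.

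The deposited values are log ratios of the channels, 1 value per feature and array, for 9728 features with 8 missing values. How the authors corrected background, normalized and took logs is not given in the sources used here. Array medians lay within 0.1 of 0, so the values were used as deposited without further centring. That limit was set beforehand for log2 values and was applied to the deposited scale without conversion. Replicates of opposite channel order correlated above 0 in 13 of 13 pairs, so the values were taken as already turned to 1 direction, and no sign was changed. Each pair lies within 1 comparison, so the pairs do not show that different days run in the same direction, which every change between days of the side arrays assumes. Day 0 correlated with days 7, 14, 21 and 28 at -0.156, -0.194, -0.0132 and 0.165 over all features, which does not settle it. For days 7 and 14 the pairs do not show a direction even within the day. After a running median along the rows was subtracted, they correlated at 0.0108 and -0.0542 at day 7 and at -0.0235 and -0.230 at day 14. Which direction that is was read as adaxial over abaxial and later over earlier day. The log base is not stated. Folds were computed for base 10, a choice made from the size of the values and not tested. The plan assumed log2 values, and the values were kept on the deposited scale instead. Fold thresholds were converted for base 10, and the limit for centring was not. Signal intensities were not analysed here.

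Features were joined to gene symbols through the platform annotation, which gave 336 features 1 symbol each, of 237 symbols, 235 of which matched the reference table of the Glycine_max 4.0 assembly. No feature was filtered out. A feature-wise linear model was fitted with limma 3.58.1 in R 4.3.3 (statmod 1.5.0). The side model had 1 coefficient for each of 5 days and a feature-specific dye term (8 residual and 3.8 prior degrees of freedom). The time model had days 14, 21 and 28 against day 7 and a dye term (4 residual and 3.31 prior). Moderated tests were two-sided, and p-values were adjusted by Benjamini and Hochberg within each contrast, with 0.05 as the threshold. Differences of the side ratio between each later day and day 0, and an F-test over days 7 to 28, came from the side model. Each standard error is that of the model. The n beside it counts the arrays that compare those samples directly. In the time model the value and its error also draw on the other arrays of the loop. Residuals of side arrays with the same replicate number correlated above 0.1 in 19 of 26 pairs around the group means and in 2 of 26 pairs after the dye term. All side arrays of replicate 1 had the same channel order and all of replicate 2 the opposite one. The dye term therefore takes up much of such a pairing, and the fall does not show that pairing is absent. In the time family it was 6 of 12 pairs either way. Replicate numbers were not treated as pairs, and a pairing in the side family was not excluded.

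Gene lists were fixed before the data were examined as text patterns on annotation. The files gave symbols and no descriptions, so membership was set by hand from the symbols afterwards. Lists with at least 5 features were tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation, fry, and no dye term. With an estimated correlation camera also uses the few residual degrees of freedom of the fit. A call lost in that form therefore need not reflect correlation between genes. These were seed storage, seed maturation and oil body, protease inhibitors and lectins (7 features of protease inhibitors, with no lectin measured), glutathione transferase and antioxidant, peroxidase, phenylpropanoid and isoflavonoid, lipoxygenase, ubiquitin and proteolysis, and aquaporin and membrane transport. Smaller ones were photosynthesis, cell division, ribosomal proteins, auxin response, cell wall, heat shock, embryo regulators, leaf polarity, starch metabolism and epidermis. Translation factors, defence, gibberellin, ethylene and abscisic acid, and vascular tissue had 0 features and gave no result. A fatty acid synthesis list was added after the data were seen. Where no form of the list test is named, the call is that of camera at the preset correlation. Fry called further lists in several comparisons, not all of which are given below.

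The rule for named genes was fixed beforehand. It took, for each contrast, the 6 annotated features with the largest positive and the 6 with the largest negative value among those past the threshold with the same sign on every array, 1 feature per symbol, and the 2 members with the smallest p of at most 6 lists. Lists were ranked by camera p. Members of lists given beyond these, such as vegetative storage clones, were chosen after their values were seen.

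Alternatives fixed beforehand were no dye term, arrays centred on their medians, arrays scaled to the same median absolute value, features with a value on every array, a robust prior, a minimum change (treat, log2 change of 0.5), all 24 arrays in 1 fit, features of 1 symbol averaged, a replicate block, each day alone, direct arrays only, a 2-fold rule on every array without a test, and leaving out each array in turn. Where that left a day with 1 or 2 arrays, the spread was pooled over the other days, and a lone array was assumed to vary like them. Alternatives added after the data were seen were subtraction of a running median over 50 rows on either side, extreme values beyond 1.5 set to missing, and an absolute log ratio of at least 1 on the replicate arrays. The fit was tested on simulated data.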

Results

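Transcript levels were compared in immature soybean (Glycine max) cotyledons cultured on 2,4-D, a synthetic auxin used to induce somatic embryos. The measurements were 24 dual-channel cDNA arrays, each giving log ratios between a pair of RNA samples at 9728 features. A feature is 1 spotted cDNA clone. The first set compared the adaxial side of cotyledons of 4 to 6 mm with the abaxial side on 14 arrays, 2 at day 0 and 3 each at days 7, 14, 21 and 28 on 40 mg/L 2,4-D. The adaxial side is the one that faces the embryo axis. The second set followed adaxial tissue through culture on 8 arrays, with 2 arrays of opposite channel order for each of day 14 against 7, day 21 against 14, day 28 against 21 and day 28 against 7. The third set held 2 arrays, 1 at day 14 and 1 at day 21, on which biological replicate G was set against biological replicate F of adaxial tissue.

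Array medians lay between -0.0284 and 0.0235. The standard deviation across features was 0.0929 to 0.190 on the side arrays, 0.152 to 0.202 on the time arrays and 0.0496 and 0.0577 on the replicate arrays. For arrays the number of replicates limits the precision. The log base is not given in the sources used here, so folds are stated only as they would be for base 10. Positive values were read as higher on the adaxial side or at the later day. That reading is not stated by the labels. That the arrays within days 7 and 14 run in the same direction, and that all days of the side arrays do, was assumed. If a single day ran the other way, its signs would swap, and so would its part in each change from day 0 and among days. A gene symbol was attached to 336 features (237 symbols), and 9392 features had none, so the counts cover all features and the named results cover a small part. A cDNA clone can also bind transcripts of closely related genes. Only F and G are called biological replicates by the labels, so the p-values of the other arrays may measure technical spread between arrays. Gene positions refer to assembly Glycine_max version 4.0.

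At day 0, before culture, protease inhibitor, seed storage and lipoxygenase transcripts were lower on the adaxial than on the abaxial side. BBI, a Bowman-Birk protease inhibitor of seeds, had a log ratio of -0.718 ± 0.0466 (SE, n = 2 arrays), which is 5.22-fold lower if the logs are base 10 (limma, adjusted p = 9.44e-06). The gene lies on chromosome 9 at 39104792 to 39105439. D-II, another Bowman-Birk inhibitor, stood at -0.639 ± 0.0615 and -0.615 ± 0.0479 on its clones. LOC547818, whose position on chromosome 9 (39088119 to 39088655) is close to that of BBI, stood at -0.541 ± 0.0513. On the other side, CYP98A2, a cytochrome P450 of the phenylpropanoid pathway, was higher in adaxial tissue at 0.256 ± 0.0428 (adjusted p = 0.00644). That value is of 1 clone, and the further CYP98A2 clones were not called.

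The protease inhibitor list, in which no lectin was measured, had 4 of 7 features lower and none higher at day 0, with a median of -0.242 (camera, adjusted p = 2.24e-16, and adjusted p = 0.000776 with an estimated correlation). Adjusted over the list alone, 6 features passed. Of 27 seed storage features 7 were lower and none higher, 18 adjusted over the list alone, with a median of -0.137 (adjusted p = 1.6e-15). The lower ones included P34, a thiol-protease-like seed vacuole protein, at -0.290 ± 0.0462, the glycinin GY5 at -0.235 ± 0.0298, and CG-1, a beta-conglycinin subunit, at -0.221 ± 0.0328. Of 14 lipoxygenase features 5 were lower, 9 adjusted over the list alone, with a median of -0.148 (adjusted p = 8.11e-15). LOX1.1 stood at -0.359 ± 0.0659 and LOX2 at -0.232 ± 0.0391. These seed lipoxygenase genes are neighbours on chromosome 13, at 43135621 to 43139890 and 43128326 to 43132622. Storage and lipoxygenase calls held with an estimated correlation (adjusted p = 0.000776 and 0.000351).

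The phenylpropanoid list was higher in adaxial tissue at day 0, with a median of 0.0528 (adjusted p = 0.00368, and adjusted p = 0.0213 with an estimated correlation), although only CYP98A2 of its 17 features passed and 2 passed adjusted over the list alone. The glutathione transferase and antioxidant list (median -0.0251, adjusted p = 0.0199) and the peroxidase list (median -0.0341, adjusted p = 0.0199) were called lower. These calls ended at adjusted p = 0.0576 and 0.116 with an estimated correlation. In the former list GSTF5, a glutathione transferase, was the feature called (-0.184 ± 0.0354, adjusted p = 0.0158), and no peroxidase passed. The seed maturation, proteolysis and transport lists did not pass (adjusted p = 0.498, 0.401 and 0.434). In all, 199 features differed between the sides, 44 higher and 155 lower, of which 23 had a symbol. With arrays scaled to the same median absolute value 883 passed, and the share that was higher moved from 22.1% to 50.6%. Without replicate 1 of day 0 the count was 65, and without replicate 2 it was 73.

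At day 7 the inhibitor and storage lists were no longer called lower, and the named differences were small. Of 7 inhibitor features 1 was lower and none higher, and of 27 storage features 3 were higher and 1 lower. LOC547892 was higher on the adaxial side at 0.270 ± 0.0365 (SE, n = 3 arrays, adjusted p = 0.00748). Of 14 lipoxygenase features 4 were higher and none lower, 5 adjusted over the list alone, among them LOX1.1 at 0.240 ± 0.0545 and VLXB, a vegetative lipoxygenase, at 0.182 ± 0.0407. GM2S-1, a 2S albumin, was higher at 0.164 ± 0.0431, and AUX28, an Aux/IAA auxin response gene, at 0.144 ± 0.0364. Lower were MS at -0.269 ± 0.0607, the seed maturation gene PM12 at -0.188 ± 0.0311, SAMDC, of polyamine synthesis, at -0.163 ± 0.0348, the vacuolar processing enzyme VPE at -0.135 ± 0.0324 and the aspartic protease SOYAP1 at -0.132 ± 0.0269. Of the PM12 clones only 1 was called.

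None of the 9 lists with at least 5 members passed at day 7 (camera; 2 had an unadjusted p under 0.05, and fry called 2). The smallest adjusted p was that of the proteolysis list, 0.0905, with a median of -0.0233. Lipoxygenases had a median of 0.0699, peroxidases 0.0906, glutathione transferases -0.0347 and seed maturation genes -0.0492, each at adjusted p = 0.148. Seed storage had a median of 0.0205 and a test that pointed down, and the phenylpropanoid list a median of 0.0258 and a test that pointed down, at adjusted p = 0.948 each. The inhibitor list (median -0.00805) and the transport list (median -0.0218) both had adjusted p = 0.321. The storage median became -0.00142 with arrays centred on their medians.

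The day 7 count was 875 features, 593 higher and 282 lower, with 34 annotated ones among them. It depended on a smooth trend along the order of the rows. After the running median of neighbouring rows was subtracted, an alternative chosen after the data were seen, 9 features passed and no named one did, LOC547892 being closest at 0.214 ± 0.0392 and adjusted p = 0.0794 (0.000698 to 1 over its alternatives). The median size of the 875 differences went from 0.137 (median SE 0.0315) to 0.0677 (median SE 0.0303). Centring the arrays gave 512 features and moved the share that was higher from 67.8% to 27.7%. The count fell to 71 without replicate 1 of day 7, the 1 array of its channel order, and to 280 without its replicate 2. It was 361 and 360 without replicates 1 and 2 of day 0, 514 without replicate 2 of day 14, 462, 491 and 350 without replicates 1, 2 and 3 of day 21, and 450 without replicate 1 of day 28. With no dye term it was 188.

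At day 14 the albumin A1 stood out as higher on the adaxial side, at 0.716 ± 0.0638 (SE, n = 3 arrays, adjusted p = 0.000513), which is 5.20-fold if the logs are base 10. The Kunitz trypsin inhibitor KTI3 was higher at 0.224 ± 0.0442, CG-1 at 0.223 ± 0.0268, the glycinin GY1 at 0.181 ± 0.025, and LOX1.1 at 0.171 ± 0.0343. 4CL3, a 4-coumarate ligase of the phenylpropanoid pathway, was higher at 0.187 ± 0.0371. Lower were LOC100037476 at -0.315 ± 0.0818, the matrix metalloproteinase MMP2 at -0.295 ± 0.0425, LOC100037452 at -0.277 ± 0.0347, LOC547791 at -0.263 ± 0.0415 and PGMPM19 at -0.212 ± 0.0463.

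Lipoxygenases formed the group that was higher at day 14 in each form of the list test, with 3 of 14 features higher, 6 adjusted over the list alone, and a median of 0.0821 (adjusted p = 0.000632, and adjusted p = 0.0317 with an estimated correlation). Seed storage had 4 features higher and 3 lower, 12 adjusted over the list alone, with a median of 0.0546 (adjusted p = 0.00144, and adjusted p = 0.082 with an estimated correlation). The lower ones were clones of the vegetative storage proteins VSPA, at -0.156 and -0.121, and LOC547820, at -0.146. The inhibitor list had KTI3 higher on 2 clones of 7 features, 2 adjusted over the list alone, with a median of 0.0753 (adjusted p = 0.00144, and adjusted p = 0.082 with an estimated correlation). Peroxidases had PRX2 higher at 0.142 ± 0.0306, 3 features adjusted over the list alone, and a median of 0.0577 (adjusted p = 0.0393, and adjusted p = 0.197 with an estimated correlation).

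With camera the other lists did not pass at day 14, while fry called the proteolysis list lower (adjusted p = 0.0283). The seed maturation median was -0.0195 while its mean was 0.00177 and its test pointed up (adjusted p = 0.751). The glutathione transferase median was -0.0241 with a test that pointed up (adjusted p = 0.865), and the transport list had a median of 0.0140 and a mean of -0.0088 (adjusted p = 0.844). The phenylpropanoid list (median 0.0126) had adjusted p = 0.467 and the proteolysis list (median -0.0243) adjusted p = 0.489, with both SOYAP1 clones lower at -0.144 and -0.119. In all 858 features differed, 265 higher and 593 lower. After subtraction of the running median 223 passed, of which 181 were among the 858, with A1, KTI3, CG-1, GY1 and MMP2 among them. Centring moved the share that was higher from 30.9% to 47.9%. The count was 216, 159 and 259 without replicates 1, 2 and 3 of day 14, and 8 when the day was fitted alone without the dye term.

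At day 21 seed reserve transcripts were higher on the adaxial side. A1 stood at 0.583 ± 0.0638 (SE, n = 3 arrays), and GY1 at 0.496 ± 0.025, which is 3.13-fold if the logs are base 10 (adjusted p = 1.9e-06). The seed lipoxygenases LOX1.1, LOX2 and LOX3 stood at 0.486 ± 0.0545, 0.402 ± 0.0294 and 0.368 ± 0.0395. BBI was now higher in adaxial tissue at 0.269 ± 0.0386, GY5 at 0.246 ± 0.0246 and KTI3 at 0.242 ± 0.0442. PM34, a seed maturation protein, was higher at 0.207 ± 0.0260 and the peroxidase PRX2 at 0.225 ± 0.0354.

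Of 14 lipoxygenase features 11 were higher and none lower at day 21, 11 adjusted over the list alone, with a median of 0.304 (adjusted p = 5.91e-14, and adjusted p = 0.000389 with an estimated correlation). Of 27 storage features 17 were higher and 1 lower, 21 adjusted over the list alone, with a median of 0.176 (adjusted p = 1.06e-12, and adjusted p = 0.00237 with an estimated correlation). The lower one was BG7S-1, a basic 7S globulin, at -0.149. Of 7 inhibitor features 4 were higher, 6 adjusted over the list alone, with a median of 0.175 (adjusted p = 1.26e-05, and adjusted p = 0.0225 with an estimated correlation). Seed maturation (5 of 11 features higher, 5 adjusted over the list alone, median 0.147, adjusted p = 3.06e-05) and peroxidase (2 of 5 higher, 3 adjusted over the list alone, median 0.0613, adjusted p = 0.0108) were also called. Both calls ended at adjusted p = 0.109 with an estimated correlation.

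Lower on the adaxial side at day 21 were MMP2 at -0.261 ± 0.0425, EN1 at -0.260 ± 0.0294, LOC547791 at -0.247 ± 0.0415, the vacuolar processing enzyme VPE2 at -0.238 ± 0.0328, the transcription factor MYB182 at -0.237 ± 0.0496 and p20-1 at -0.236 ± 0.0376. The proteolysis list went both ways, with 2 features higher and 4 lower (median -0.0274, adjusted p = 0.744), since 2 VPE clones were higher. The glutathione transferase list (median -0.00695 with a test that pointed up) and the transport list (median 0.0101, mean -0.00207) both had adjusted p = 0.708. The phenylpropanoid list had a median of -0.0117, a mean of 0.0029 and adjusted p = 0.616. The count was 1822 features, 735 higher and 1087 lower, whereas 59 of the 98 annotated ones were higher. Centring moved the share that was higher from 40.3% to 66.0%. Without replicates 1, 2 and 3 of day 21 the count was 744, 387 and 919.

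At day 28 camera called none of the storage, inhibitor and lipoxygenase lists between the sides, and the annotated features with large differences were of other kinds. CAB3, a chlorophyll-binding protein, was higher on the adaxial side at 0.30 ± 0.0587 (SE, n = 3 arrays, adjusted p = 0.00393), RPL2, a ribosomal protein, at 0.229 ± 0.0352, and LOC547870, a nucleoside diphosphate kinase, at 0.204 ± 0.0342. GR and LOC547605 were higher at 0.275 ± 0.0338 and 0.276 ± 0.0433. Lower were p20-1 at -0.583 ± 0.0376, which is 3.83-fold if the logs are base 10 (adjusted p = 4.64e-06), LOC547801 at -0.363 ± 0.0312, the biotin carboxylase ACCC-3 of acetyl-CoA carboxylase at -0.333 ± 0.0949, and the seed coat peroxidase Ep at -0.30 ± 0.0329.

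The proteolysis list was the one list of 9 that camera called at day 28, while fry called 5 and camera with no dye term called 4. It had 1 feature higher and 6 lower of 11, 8 adjusted over the list alone, and a median of -0.0833 (adjusted p = 0.0283, and adjusted p = 0.141 with an estimated correlation). VPE2 was lower at -0.198 ± 0.0328 and a VPE clone higher at 0.122 ± 0.0301. Of 12 glutathione transferase and antioxidant features 6 were lower and 1 higher, 9 adjusted over the list alone, with GSTL3 at -0.267 ± 0.0368 and GSTF5 at 0.178 ± 0.0293, but the list did not pass with camera (median -0.119, adjusted p = 0.0548, fry 0.00118, camera with no dye term 0.0295). The inhibitor list had a median of -0.108 and the same adjusted p of 0.0548, with BBI lower at -0.143 ± 0.0386. Fry called the inhibitor list (adjusted p = 0.00717), as did camera with no dye term (adjusted p = 0.019). Lipoxygenases had a median of 0.0771 (adjusted p = 0.0545, fry 0.00219, camera with no dye term 0.0117) and 1 feature higher, LOX2 at 0.126 ± 0.0323. Storage features split into 5 higher and 3 lower, 13 adjusted over the list alone (median 0.0211, adjusted p = 0.582), clones of P34 and the glycinins GY1, GY2 and GY5 being higher while 2 CG-1 clones and BG7S-1 were lower.

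Peroxidases had a median of 0.00551, a mean of -0.0764 and adjusted p = 0.508 at day 28. Seed maturation (median -0.0181, adjusted p = 0.652), the phenylpropanoid list (median -0.011, adjusted p = 0.797) and transport (median -0.0391, adjusted p = 0.491) did not pass. The count was 2064 features, 1186 higher and 878 lower, with 90 annotated ones among them. It was 963 without replicate 1 of day 28. Days 14 and 21 shared 412 called features, 408 of them in the same direction, and days 21 and 28 shared 800, 775 in the same direction. The earlier neighbouring days shared few: 79 at days 7 and 14, 56 in the same direction, and 22 at days 0 and 7, 10 in the same direction. Of 85 features called at days 0 and 21, 62 had opposite signs, whereas of 70 called at days 0 and 28, 25 had opposite signs.

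**Figure D1:**
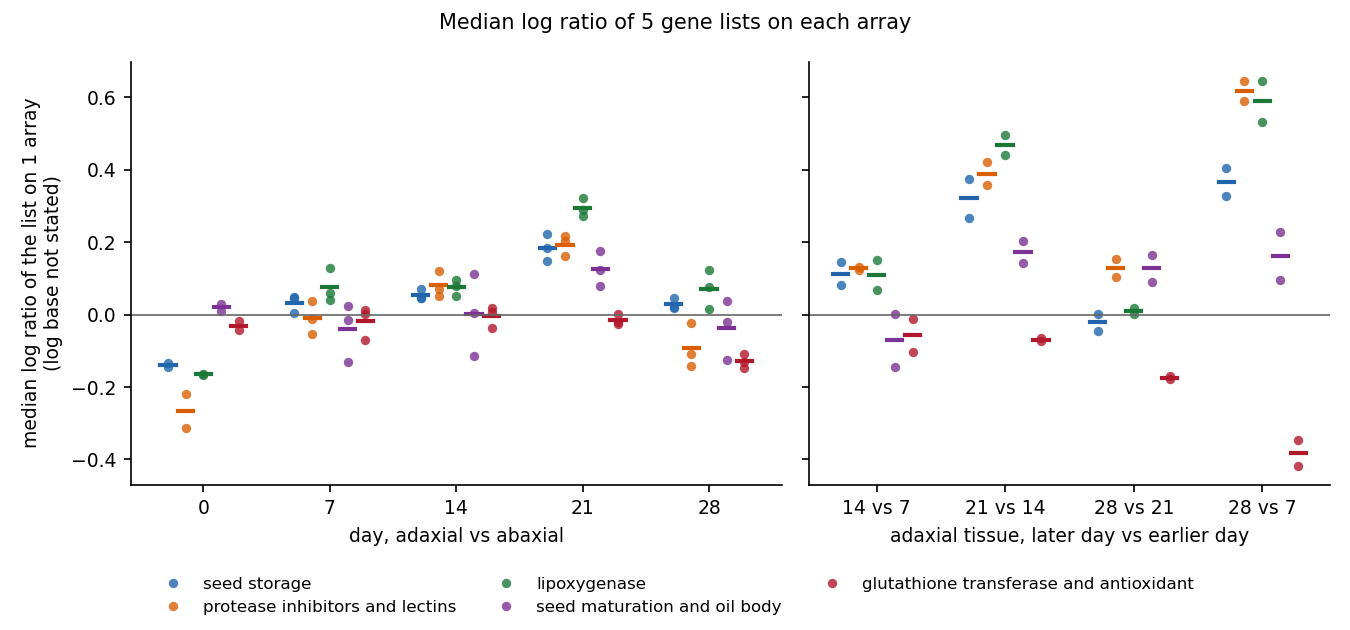
Median log ratio of 5 gene lists on each array (points) and the mean over arrays (bars), between the sides by day and for each time comparison. In the fit the lipoxygenase median went from -0.148 at day 0 to 0.304 at day 21, and the seed storage median from -0.137 to 0.176.

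The change of the side ratio from day 0 was tested directly, as a difference between days. By day 7 the ratio of the inhibitors had risen: D-II by 0.738 ± 0.0798 (SE), or 5.47-fold if the logs are base 10 (adjusted p = 0.000417), and BBI by 0.619 ± 0.0605. LOX1.1 rose by 0.599 ± 0.0856, LOX2 by 0.354 ± 0.0507, GY5 by 0.323 ± 0.0386 and CG-1 by 0.282 ± 0.0426. These are the clones with the larger changes. Other clones stood at 0.224 for LOX1.1, 0.0346 for GY5 (limma, adjusted p = 0.729) and 0.101 for CG-1 (adjusted p = 0.402). LOC547931, a beta-amylase, rose by 0.470 ± 0.0414. The ratio fell for PM12 (-0.274 ± 0.0489), CYP98A2 (-0.243 ± 0.0555), SOYAP1 (-0.189 ± 0.0423) and OAS-TL4, of cysteine synthesis (-0.160 ± 0.0374). Further CYP98A2 clones stood at -0.0709 and -0.0591 and were not called (limma, adjusted p = 0.508 and 0.585). Nor were further PM12 clones, at -0.170 and -0.134 (limma, adjusted p = 0.106 and 0.172).

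From day 0 to day 7 the lipoxygenase list rose by a median of 0.214 (5 of 14 features, 10 adjusted over the list alone, adjusted p = 1.49e-07), storage by 0.163 (6 of 27, 13 adjusted over the list alone, adjusted p = 5.41e-06) and inhibitors by 0.234 (3 of 7, 5 adjusted over the list alone, adjusted p = 7.7e-06). With an estimated correlation these had adjusted p = 0.00365, 0.0201 and 0.0201. The peroxidase list rose (median 0.125, adjusted p = 0.0233, and adjusted p = 0.124 with an estimated correlation), with no feature passing over all features and 3 adjusted over the list alone. The phenylpropanoid list fell (median -0.0512, 1 feature, adjusted p = 0.0399, and adjusted p = 0.0879 with an estimated correlation). Seed maturation (median -0.0735), glutathione transferases (0.0128), proteolysis (-0.00263) and transport (-0.0509) did not pass, at adjusted p = 0.11, 0.878, 0.259 and 0.705. The count was 273 features, 170 up and 103 down. It was 71 and 63 without replicates 1 and 2 of day 0, 170 without replicate 3 of day 21, and 145 after subtraction of the running median.

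From day 0 to day 14 the ratio of BBI rose by 0.819 ± 0.0605, or 6.59-fold if the logs are base 10 (adjusted p = 3.28e-05), A1 by 0.742 ± 0.10, D-II by 0.691 ± 0.0621, LOX1.1 by 0.514 ± 0.0856, KTI3 by 0.462 ± 0.0718 and CG-1 by 0.441 ± 0.0420. GSTF5 rose by 0.257 ± 0.0460. The ratio fell for LOC100037452 (-0.337 ± 0.0545), CYP98A2 (-0.325 ± 0.0555), the vegetative storage genes VSPA (-0.318 ± 0.0561) and LOC547820 (-0.309 ± 0.0573), MMP2 (-0.291 ± 0.0666), CEL12, a cellulase (-0.289 ± 0.0668), and HGS, a homoglutathione synthetase (-0.246 ± 0.0438).

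The inhibitor list rose from day 0 to day 14 in 6 of 7 features, 6 adjusted over the list alone (median 0.462, adjusted p = 6.77e-12). Storage rose in 11 and fell in 3 of 27, 18 adjusted over the list alone (median 0.198, adjusted p = 1.27e-11), and lipoxygenases rose in 7 of 14, 10 adjusted over the list alone (median 0.254, adjusted p = 1.61e-11). With an estimated correlation these had adjusted p = 0.00215, 0.00215 and 0.000931. Peroxidases rose in 2 of 5, PRX2 on both clones, with 2 adjusted over the list alone (median 0.0918, adjusted p = 0.00807, and adjusted p = 0.0995 with an estimated correlation). With camera the glutathione transferase (median 0.0458), phenylpropanoid (-0.0818) and transport (0.0276, mean -0.00321) lists did not pass, at adjusted p = 0.173, 0.454 and 0.642. Fry called the phenylpropanoid list lower (adjusted p = 0.00719). Of its features 1 was called over all features, a CYP98A2 clone, so the further CYP98A2 clones were not. Seed maturation (median -0.0687 with a test that pointed up) and proteolysis (-0.00693) both had adjusted p = 0.998.

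The count from day 0 to day 14 was 566 features, 259 up and 307 down, and 35 of the 52 annotated ones were up. Centring moved the share that was up from 45.8% to 70.5%, and scaling moved it to 33.1%. The count was 78 and 118 without replicates 1 and 2 of day 0, and 333 and 280 without replicates 1 and 2 of day 14. It was 285 after subtraction of the running median.

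From day 0 to day 21 the ratio of BBI rose by 0.987 ± 0.0605, or 9.69-fold if the logs are base 10 (adjusted p = 5.64e-06). LOX1.1 rose by 0.845 ± 0.0856, D-II by 0.792 ± 0.0798, GY1 by 0.667 ± 0.0392, LOC547818 by 0.665 ± 0.0665, A1 by 0.609 ± 0.10, LOX2 by 0.591 ± 0.0462, GY5 by 0.481 ± 0.0386, GSTF5 by 0.342 ± 0.0460, PRX2 by 0.325 ± 0.0556 and the seed maturation gene PM29 by 0.273 ± 0.0611. It fell for the transcription factor NAC1 (-0.319 ± 0.0480), CYP98A2 (-0.297 ± 0.0555), LOC100037452 (-0.274 ± 0.0545), LOC547791 (-0.269 ± 0.0652), MMP2 (-0.257 ± 0.0666) and HGS (-0.168 ± 0.0438).

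Storage features rose from day 0 to day 21 in 20 of 27 and fell in 2, which were clones of VSPA and LOC547820, with 27 passing adjusted over the list alone (median 0.365, adjusted p = 2.15e-20). Lipoxygenases rose in 10 of 14, 11 adjusted over the list alone (median 0.493, adjusted p = 3.71e-20), and inhibitors in 6 of 7, 6 adjusted over the list alone (median 0.454, adjusted p = 4.16e-13). With an estimated correlation the adjusted p were 0.000407, 0.000102 and 0.00134. Peroxidases rose in 2 of 5, 2 adjusted over the list alone (median 0.0548, adjusted p = 0.00166, and adjusted p = 0.0552 with an estimated correlation). Seed maturation genes rose in 2 of 11, 4 adjusted over the list alone (median 0.125, adjusted p = 0.00266, and adjusted p = 0.223 with an estimated correlation). Glutathione transferases (median 0.0208), the phenylpropanoid list (-0.0548, 3 features down), proteolysis (-0.0239 with a test that pointed up) and transport (-0.0218, mean 0.00352) had adjusted p = 0.141, 0.335, 0.875 and 0.445.

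The count from day 0 to day 21 was 786 features, 428 up and 358 down, and 50 of the 71 annotated ones were up. Centring moved the share that was up from 54.5% to 80.6%, and scaling moved it to 42.3%. The count was 244 and 238 without replicates 1 and 2 of day 0, and 478, 401 and 484 without replicates 1, 2 and 3 of day 21.

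From day 0 to day 28 the ratio of BBI rose by 0.574 ± 0.0605, or 3.75-fold if the logs are base 10 (adjusted p = 0.000342), LOX1.1 by 0.523 ± 0.0856, D-II by 0.502 ± 0.0621, LOC547818 by 0.403 ± 0.0665, P34 by 0.395 ± 0.0599, GY5 by 0.389 ± 0.0386, GSTF5 by 0.362 ± 0.0460 and GY1 by 0.321 ± 0.0392. It fell for p20-1 (-0.428 ± 0.0590), LOC547837 (-0.337 ± 0.0605), LOC547801 (-0.326 ± 0.0489), NAC1 (-0.284 ± 0.0480), Ep (-0.271 ± 0.0517), GSTL3 (-0.271 ± 0.0578) and CYP98A2 (-0.242 ± 0.0555).

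Lipoxygenases rose from day 0 to day 28 in 8 of 14 features, 11 adjusted over the list alone (median 0.217, adjusted p = 9.19e-09), storage in 6 of 27 with 1 down, 13 adjusted over the list alone (median 0.128, adjusted p = 1.19e-06), and inhibitors in 3 of 7, 4 adjusted over the list alone (median 0.146, adjusted p = 1.98e-05). With an estimated correlation the adjusted p were 0.00216, 0.0201 and 0.0251. The phenylpropanoid (median -0.0732) and proteolysis (-0.0821) lists had adjusted p = 0.0523 and 0.0587. Of the former list 1 feature was called, a CYP98A2 clone that fell, so the further CYP98A2 clones were not. Seed maturation (-0.0563), glutathione transferases (-0.0659), peroxidases (0.0448, mean -0.0269) and transport (-0.00105) had adjusted p = 0.483, 0.477, 0.963 and 0.771. The count was 621 features, 356 up and 265 down, and centring moved the share that was up from 57.3% to 69.1%. It was 178 and 117 without replicates 1 and 2 of day 0, and 302 without replicate 1 of day 28.

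Among days 7, 14, 21 and 28 the side ratio of 2145 features changed (limma F-test that the 4 coefficients are equal). The count was 1239 without replicate 1 of day 7, 1408 and 1144 without replicates 1 and 2 of day 21, and 1149 without replicate 1 of day 28. With no dye term it was 1042, and after subtraction of the running median it was 961.

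**Figure D2:**
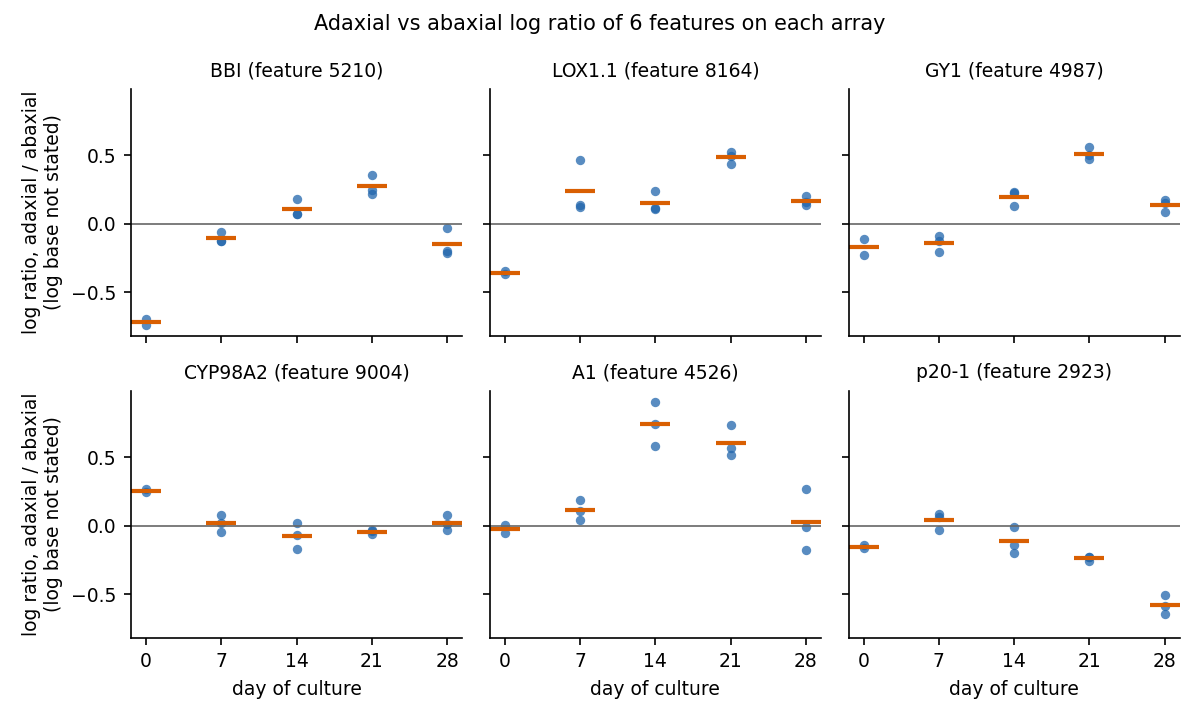
Log ratio of 6 named features by day of culture between the sides, with each array as a point and the mean as a bar. BBI stood at -0.718 at day 0 and at 0.269 at day 21, and p20-1 at -0.583 at day 28.

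In adaxial tissue from day 7 to day 14, A1 rose by 0.686 ± 0.0866 (SE, n = 2 arrays), or 4.85-fold if the logs are base 10 (adjusted p = 0.000915). This and the later time values come from the loop fit of 8 arrays, 2 of which compare the named days directly. Also up were p20-1 at 0.553 ± 0.0255, the peroxidase PRX2 at 0.440 ± 0.0225, MMP2 at 0.427 ± 0.0190, LOC547605 at 0.360 ± 0.0307 and CG-1 at 0.304 ± 0.0230. Down were VPE at -0.461 ± 0.0285, the seed maturation gene PM40 at -0.454 ± 0.0240, the AAA ATPase CDC48 at -0.439 ± 0.0381, the flavonol synthase FLS1 at -0.288 ± 0.0280, and CYSTATIN, a cysteine protease inhibitor, at -0.277 ± 0.0292.

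Seed storage rose from day 7 to day 14 in 14 of 27 features and fell in 1, a GY2 clone, with 15 adjusted over the list alone (median 0.0873, adjusted p = 0.0171). Peroxidases rose in 4 of 5, 4 adjusted over the list alone (median 0.205, adjusted p = 0.0316), and lipoxygenases rose in 8 and fell in 1 of 14, 9 adjusted over the list alone (median 0.114, adjusted p = 0.0316). Proteolysis fell in 7 and rose in 1 of 11, 8 adjusted over the list alone (median -0.129, adjusted p = 0.0171), and seed maturation fell in 6 of 11, 6 adjusted over the list alone (median -0.102, adjusted p = 0.0455). None of these 5 calls held with an estimated correlation. For storage, peroxidase and proteolysis that gave adjusted p = 0.199 with an estimated correlation, for lipoxygenases 0.43 and for seed maturation 0.276. The estimate itself was -0.07 for proteolysis and 0.00972 for peroxidase, below the preset 0.01. Those losses thus did not come from a stronger correlation of their own genes. For storage the estimate was 0.0361, for seed maturation 0.0783 and for lipoxygenases 0.361. Inhibitors (median 0.151) had adjusted p = 0.0632, with 6 features up and CYSTATIN down. Glutathione transferases (median -0.0697), transport (-0.0488) and the phenylpropanoid list (0.0334, 6 up and 5 down) had adjusted p = 0.201, 0.362 and 0.628. The count was 5325 features, 2772 up and 2553 down, and it was 3279 without replicate 2 of that comparison.

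From day 14 to day 21 most features of the storage, inhibitor and lipoxygenase lists rose in adaxial tissue. A1 rose by 0.802 ± 0.0866 (SE, n = 2 arrays), or 6.33-fold if the logs are base 10 (adjusted p = 0.000504), LOX1.1 by 0.771 ± 0.0554, LOX2 by 0.640 ± 0.0402, LOX3 by 0.602 ± 0.0177, BBI by 0.591 ± 0.0430, CG-1 by 0.534 ± 0.0230, GY3 by 0.438 ± 0.0181, PM34 by 0.434 ± 0.0281 and KTI3 by 0.392 ± 0.0176. PRX2 rose by 0.358 ± 0.0225 and PM40 by 0.270 ± 0.0240. Down were MMP2 at -0.356 ± 0.0190, GSTL3 at -0.314 ± 0.0315, the isoflavone synthase IFS2 at -0.299 ± 0.0202 and 4CL3 at -0.244 ± 0.0209. LOC547652 (-1.45 ± 0.518), CYP93E1, a cytochrome P450 of triterpenoid synthesis (-0.661 ± 0.205), LOC100037476 (-0.644 ± 0.170) and ACCC-3 (-0.463 ± 0.121) also passed, with large errors. For LOC100037476 the value was 0.0336 when features of 1 symbol were averaged (adjusted p = 0.584, and 0.000999 to 0.584 over its alternatives).

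Storage rose from day 14 to day 21 in 22 of 27 features and fell in 4, with 26 adjusted over the list alone (median 0.368, adjusted p = 1.27e-09). The falls were VSPA on 2 clones, LOC547820 and a P34 clone. Lipoxygenases rose in 13 of 14, 13 adjusted over the list alone (median 0.483, adjusted p = 1.27e-09), inhibitors in 7 of 7, 7 adjusted over the list alone (median 0.391, adjusted p = 1.15e-05), seed maturation in 9 of 11, 9 adjusted over the list alone (median 0.194, adjusted p = 0.000131), and peroxidases in 4 of 5, 4 adjusted over the list alone (median 0.219, adjusted p = 0.00203). Storage and inhibitors held at adjusted p = 0.0456 with an estimated correlation. For lipoxygenases it was adjusted p = 0.0865 with an estimated correlation, and for seed maturation and peroxidases 0.077. The phenylpropanoid list (median -0.066, 2 up and 8 down) and glutathione transferases (-0.0643, 6 down) had adjusted p = 0.0633 and 0.0815. Proteolysis had a median of -0.078, a mean of 0.0322 and a test that pointed up (adjusted p = 0.489), and transport a median of -0.0115 with a test that pointed up (adjusted p = 0.928).

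The count from day 14 to day 21 was 5518 features, 2192 up and 3326 down. Centring moved the share that was up from 39.7% to 50.6%. Of 3866 features called in this step and the step before it, 3511 went opposite ways, 2073 up then down and 1438 down then up. Day 14 tissue is part of both comparisons, with opposite sign, which by itself favours opposite moves.

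From day 21 to day 28 the peroxidase Ep fell by 0.498 ± 0.0321 (SE, n = 2 arrays), or 3.14-fold if the logs are base 10 (adjusted p = 0.000318). The glutathione transferases GSTU30 (-0.415 ± 0.0414) and GSTa (-0.292 ± 0.06) fell, as did LOC548029 (-0.318 ± 0.0320) of the same list, LOC547801 (-0.357 ± 0.0192), MMP2 (-0.330 ± 0.0190) and IFS2 (-0.176 ± 0.0202). Up were PGMPM19 at 0.442 ± 0.0237, the seed maturation genes PM34 at 0.331 ± 0.0521 and PM41 at 0.302 ± 0.0272, BBI at 0.279 ± 0.0430, LOC547892 at 0.264 ± 0.0399 and VPE at 0.234 ± 0.0224.

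Seed maturation rose from day 21 to day 28 in 6 of 11 features, 8 adjusted over the list alone (median 0.110, adjusted p = 3.51e-05), inhibitors in 6 of 7, 7 adjusted over the list alone (median 0.121, adjusted p = 0.000155), and proteolysis in 3 of 11, 4 adjusted over the list alone (median 0.0568, adjusted p = 0.00338). Glutathione transferases fell in 6 and rose in 1 of 12, 11 adjusted over the list alone (median -0.174, adjusted p = 0.000841), and the phenylpropanoid list fell in 3 of 17, 4 adjusted over the list alone (median -0.0395, adjusted p = 0.00338). None held: for the phenylpropanoid list it was adjusted p = 0.0816 with an estimated correlation, and for the other 4 it was 0.0694. Storage (median -0.0246, 1 up and 3 down) and lipoxygenases (0.000806) had adjusted p = 0.211 and 0.503. Peroxidases had a median of 0.00238 and a mean of -0.183, with both Ep clones down (adjusted p = 0.0811), and transport had a median of -0.0306 (adjusted p = 0.0881). The count was 1235 features, 530 up and 705 down. It was 379 and 514 without replicates 1 and 2 of this comparison, 813 without replicate 1 of day 21 against 14, 775 without replicate 2 of day 28 against 7, 566 with no dye term and 2892 with arrays scaled to the same median absolute value.

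Over the whole interval from day 7 to day 28, A1 rose by 1.54 ± 0.0866 (SE, n = 2 arrays), or 34.7-fold if the logs are base 10 (adjusted p = 1.37e-05), and BBI by 1.02 ± 0.0430, or 10.5-fold. LOC547892 rose by 0.971 ± 0.0399, PRX2 by 0.832 ± 0.0225, CG-1 by 0.796 ± 0.0230, D-II by 0.780 ± 0.0456, LOX3 by 0.703 ± 0.0177, KTI3 by 0.653 ± 0.0176, PM34 by 0.626 ± 0.0281 and GY5 by 0.560 ± 0.0172. Down were LOC548030 at -0.575 ± 0.0359, GSTa at -0.573 ± 0.06, LOC548029 at -0.538 ± 0.0320, GSTU30 at -0.510 ± 0.0414, the transcription factor WRKY27 at -0.507 ± 0.0279, GSTL3 at -0.484 ± 0.0315, IFS2 at -0.335 ± 0.0202 and 4CL3 at -0.293 ± 0.0209.

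Storage rose from day 7 to day 28 in 20 of 27 features, 23 adjusted over the list alone (median 0.392, adjusted p = 1.92e-14), and inhibitors in 6 of 7, 6 adjusted over the list alone (median 0.653, adjusted p = 1.51e-06). These held at adjusted p = 0.0274 and 0.034 with an estimated correlation. Lipoxygenases rose in 14 of 14, 14 adjusted over the list alone (median 0.567, adjusted p = 1.08e-13), and seed maturation rose in 10 of 11 with PM40 down, 11 adjusted over the list alone (median 0.209, adjusted p = 2.27e-05). Both had adjusted p = 0.061 with an estimated correlation. Glutathione transferases fell in 9 and rose in 2 of 12, 11 adjusted over the list alone (median -0.330, adjusted p = 0.00225), and the phenylpropanoid list fell in 12 and rose in 1 of 17, 13 adjusted over the list alone (median -0.0988, adjusted p = 0.00214). Both had adjusted p = 0.0692 with an estimated correlation. Peroxidases (median 0.0729, 2 up), transport (-0.106) and proteolysis (-0.0598) had adjusted p = 0.0567, 0.0961 and 0.789. The count was 4171 features, 1529 up and 2642 down. Centring moved the share that was up from 36.7% to 49.9%, and without replicate 2 of this comparison the count was 2238.

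**Figure D3:**
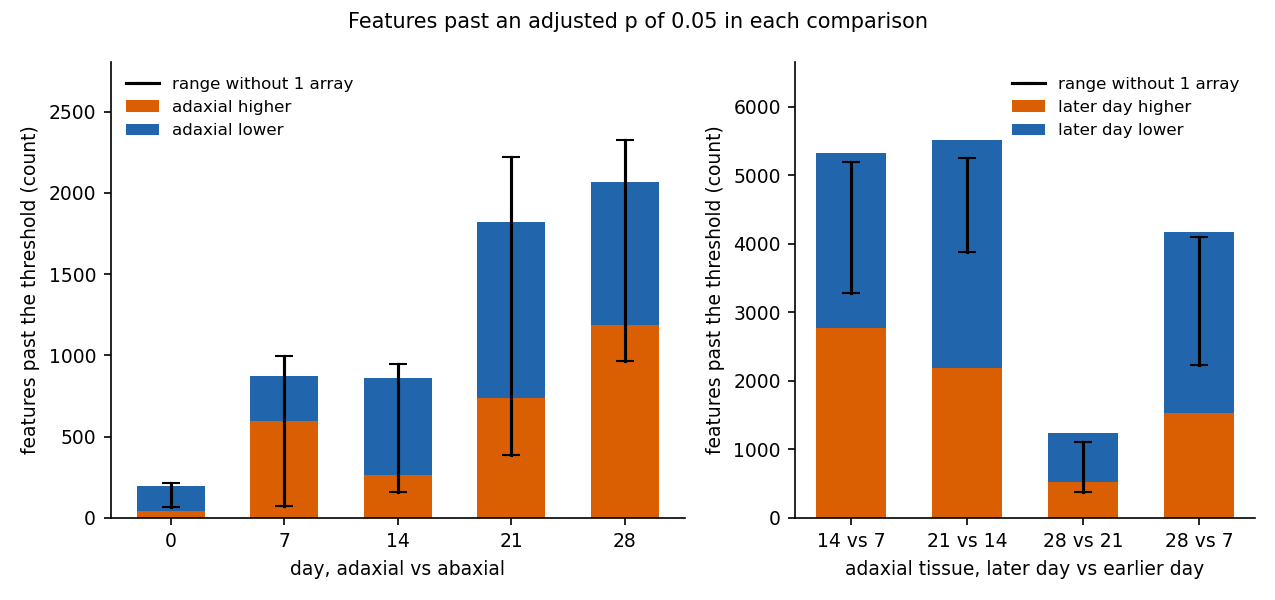
Number of features called higher or lower between the sides by day (left) and up or down in adaxial tissue by time comparison (right), with lines for the range without 1 array. Calls between the sides were 199 at day 0 on 2 arrays and 2064 at day 28 on 3 arrays. The number of arrays differed, so these counts do not measure a rise. The largest time count was 5518 from day 14 to day 21.

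The sum of the 3 steps was set against the direct comparison of day 28 with day 7 across 9721 features, which are not independent replicates. Spearman's correlation was 0.713 and Pearson's 0.662, with a slope of 0.509. With the sign of 1 step turned, Spearman's correlation was -0.0124, 0.312 or 0.168.

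On the arrays of replicate G against F, which hold no difference in day or side, 20 features at day 14 and 16 at day 21 passed 2-fold if the logs are base 10, without a test. The time arrays had 202 to 671 such features each, and the side arrays 52 to 415. Print lots differed among these sets, and the scanner differed between the side arrays and the others. Between replicates of opposite channel order, Spearman's correlation across features was 0.0315 to 0.709 in 13 pairs.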

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

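The subtraction of a running median was chosen after the data were seen, and the test of a position effect tied to the channels after the day 7 result was seen. The results below were singled out because the adaxial to abaxial ratio differed between days, in a test of the difference itself. Each of these tests assumes that the days run in the same direction. Against day 0 the ratio differed for 273 features at day 7, 566 at day 14, 786 at day 21 and 621 at day 28, and it differed among days 7 to 28 for 2145.

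By list, the seed storage ratio was higher than at day 0 by a median of 0.163 at day 7, 0.198 at day 14, 0.365 at day 21 and 0.128 at day 28. For protease inhibitors it was higher by 0.234, 0.462, 0.454 and 0.146, and for lipoxygenases by 0.214, 0.254, 0.493 and 0.217. The peroxidase ratio was higher by 0.125 at day 7, 0.0918 at day 14 and 0.0548 at day 21, and the seed maturation ratio by 0.125 at day 21. These 4 calls were lost, in that order at adjusted p = 0.124, 0.0995, 0.0552 and 0.223 with an estimated correlation. The phenylpropanoid ratio was lower than at day 0 by a median of -0.0512 at day 7, a call lost at adjusted p = 0.0879 with an estimated correlation.

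Of 48 seed storage, inhibitor and lipoxygenase features, 42 were below 0 at day 0 and above 0 at day 21, and the difference was called for 38, upward in 36. These features are clones of 10 storage, 4 inhibitor and 6 lipoxygenase genes, so they are not independent. A bias of single features for 1 dye was argued against by the median difference within each channel order, 0.344 in 1 order and 0.394 in the other, beside 0.374 in the fit. A trend along the row order was argued against by a median of 0.383 after the running median of neighbouring rows was subtracted. A candidate explanation is that cultured adaxial tissue gained seed reserve transcripts that it held at a lower level than abaxial tissue before culture. From day 14 to day 21 adaxial tissue itself rose by medians of 0.368 for storage, 0.391 for inhibitors and 0.483 for lipoxygenases (the last at adjusted p = 0.0865 with an estimated correlation), if positive values mean the later day. Over that step the side medians went, in that order, from 0.0546 to 0.176, 0.0753 to 0.175 and 0.0821 to 0.304. These moves were smaller, though no test compared them. From day 21 to day 28 adaxial tissue had medians of -0.0246, 0.121 and 0.000806, while the side medians went to 0.0211, -0.108 and 0.0771. No array follows adaxial tissue from day 0 to day 7, and none compares abaxial tissue between days. A change on the abaxial side therefore stays open at every step. The explanation stays a hypothesis. Day 0 rests on 2 arrays, and different mixes of cells on the sides were not tested. That day 0 and day 21 run in the same direction was assumed, and their correlation over all features, -0.0132, does not settle it. If day 0 ran the other way, most of these features would have 1 sign at both days and no switch would be left.

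Between the sides, 875 features were called at day 7. A trend along the row order could explain much of this, since 9 were called after the running median was subtracted. The median size of the 875 differences fell from 0.137 to 0.0677, while their median SE went from 0.0315 to 0.0303, so the calls ended with smaller differences and not with a wider spread. Of the 875, 840 kept their direction and 437 an unadjusted p under 0.05. They were picked for large values: over all 9728 features 7192 kept their direction, and the median size went from 0.0504 to 0.0319. Whether 1 array that stands apart carries them stays open. Without replicate 1 the count was 71, but that array is the only one of its channel order at day 7, so leaving it out removes that order too. The planned rule would have counted this fall for such an array, and it was set aside after the count was seen. A position effect tied to the channels cannot be told apart from a difference between the sides. The trends of replicates with opposite channel order correlated at 0.712 and 0.814, which counts against such an effect only if the day 7 values had been turned to 1 direction. These pairs do not show that, since they correlated at 0.0108 and -0.0542 after the running median was subtracted. The limit written for this test was set aside for that reason after the values were seen. Whether the row order groups clones by source library, which would make the trend biological, stays open.

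The 2145 features that changed among days 7 to 28 were set beside other splits of the 12 arrays into 4 groups of 3. Of 100 splits, only the real one, counted as 1, called as many, and the highest other called 773. That argues against a random division of the arrays. The splits used values from which no running median had been subtracted. RNA or a row-order trend shared by the arrays of a day would give the same result, so the test does not tell these apart from a change with day. For single days the 3 arrays allow 4 sign patterns, too few for a share under 0.05. The real pattern called 875, 858, 1822 and 2064 features at days 7, 14, 21 and 28, and the highest other pattern 1, 1, 0 and 1.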

How the results depend on the processing

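The running median, the removal of extreme values and the log ratio of at least 1 on the replicate arrays were chosen after the data were seen. Comparisons between the sides are given by day, and "from day 0" marks the change of the side ratio. Called-feature counts stayed within 1.5 times the reported value in 117 alternatives and went beyond it in 54. They stayed within it under a robust prior, with features that have a value on every array, with symbols averaged, with direct arrays only and with extreme values removed. Where a count went beyond it and no reason is given, the cause was not tested.

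With no dye term, counts were 188 at day 7 and 485 at day 14. From day 0 they were 169 to day 7, 307 to day 14, 516 to day 21 and 332 to day 28, and 1042 features changed among days 7 to 28. Day 28 against 21 gave 566. Centring gave 512 at day 7. Scaling gave 883 at day 0, and from day 0 it gave 1105, 1452, 1368 and 1007 to days 7, 14, 21 and 28. It gave 2892 for day 28 against 21.

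A minimum change asks for more by construction. With it, limma's treat called 52, 0, 3, 52 and 107 features at days 0, 7, 14, 21 and 28, where 2884 features at day 7 had an unadjusted p under 0.05 without it. From day 0 it called 47, 52, 101 and 82. In the time comparisons it called 189 from day 7 to 14, 324 from 14 to 21, 91 from 21 to 28 and 671 from 7 to 28. At least 2-fold (if base 10) on every array, without a test, gave 65, 1, 4, 33 and 54 between the sides and 127, 216, 81 and 409 in the same time order.

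All 24 arrays in 1 fit gave 307, 1845 and 1515 at days 0, 7 and 14. From day 0 this fit gave 720, 1060, 1287 and 1069, and 3742 features changed among days 7 to 28. Each day fitted alone without the dye term, which changes 2 choices together, gave 316, 0, 8 and 1251 at days 0, 7, 14 and 28, and the cause was not tested. After the running median was subtracted, counts were 9 at day 7 and 223 at day 14, 145 and 285 from day 0 to days 7 and 14, and 961 among days 7 to 28.

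A replicate block gave 183, 721, 777, 1559 and 2037 between the sides by day, within 1.5 times of the reported counts. It assumes a pairing by replicate number, which the dye term largely takes up in the side family.

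Leaving out 1 array lowers the number of arrays and pools the spread over the other days, so a lone array was assumed to vary like them. Between the sides the counts were 65 to 217 at day 0, 71 to 997 at day 7, 159 to 949 at day 14, 387 to 2219 at day 21 and 963 to 2326 at day 28. At days 7, 14, 21 and 28 the lowest count came without the 1 array of its channel order. From day 0 they were 63 to 344, 78 to 601, 238 to 941 and 117 to 740 for days 7, 14, 21 and 28, and 1144 to 2434 among days 7 to 28. In time order they were 3279 to 5194, 3876 to 5252, 379 to 1109 and 2238 to 4103. The loop correlation was 0.613 with replicate 1 arrays alone and 0.711 with replicate 2 arrays alone.

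Gene lists called were fewer with an estimated correlation: 1 at day 14, 3 at day 21, 0 at day 28 (camera, 9 lists), 3 from day 0 to days 7 and 21, 0 for day 14 against 7 and for day 28 against 21, and 2 for day 21 against 14 and for day 28 against 7. The estimated form also uses fewer degrees of freedom, so these falls need not come from correlation between genes. Fry called 2 lists at day 7, 5 at day 28, 5 from day 0 to day 28 and 8 for day 21 against 14. With no dye term 4 lists were called at day 28 and 5 from day 0 to day 28. The list counts stayed within 1.5 times in 37 alternatives and went beyond it in 15. The 37 include turning the sign of every array, which leaves camera p-values unchanged by construction.

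On the replicate arrays of days 14 and 21, a limit of 1.5-fold gave 60 and 86 features, scaling gave 114 and 110, and a log ratio of at least 1 gave 0 and 0, without a test. Among named features, 2691 alternatives kept direction and side of the threshold, 286 lost the call, 50 gained it and 1 reversed. The reversal was LOC100037476 from day 14 to day 21, at 0.0336 when features of 1 symbol were averaged (adjusted p = 0.584, and 0.000999 to 0.584 over its alternatives). Leaving out 1 array kept 2846, ended 279 and added 21. How signal over background limits small values was not analysed here.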

Other observations

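The tests of the rise and fall around day 14 were chosen after that result was seen, as were the fatty acid synthesis list and the features named from lists with fewer than 5 members, and the running median was chosen after the data were seen. At day 28 the adaxial side was higher for CAB3 at 0.30 and for the ribosomal proteins RPL2 at 0.229 and RPL37 at 0.131, and TUBB3, a tubulin, was higher at 0.114. At day 21 it was lower for the Aux/IAA genes AUX22 at -0.155 and AUX28 at -0.165, for CEL12 at -0.136 and for BIP4, a chaperone, at -0.144. CEL12 was also lower at day 14, at -0.190 and -0.184 on its clones. At day 7 MADS28 was higher at 0.104 (adjusted p = 0.0362).

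HDL56, a homeobox leucine zipper gene, was lower on the adaxial side at day 28 on 1 clone (-0.175) and fell from day 7 to day 28 on that clone (-0.365 ± 0.0222, adjusted p = 1.98e-05), while the other clone stood at -0.00323 over that interval. BIP4 fell from day 7 to day 28 on its clones (-0.161, -0.257 and -0.156). HPS, the 1 epidermis feature, stood at 0.0184, -0.0411, 0.0140, -0.0466 and -0.0827 between the sides by day and was never called. LOC547931 was lower on the adaxial side at day 0 (-0.350 ± 0.0319). The fatty acid synthesis list was called higher at day 0 (median 0.0619, adjusted p = 0.0145, and adjusted p = 0.103 with an estimated correlation), from day 14 to day 21 (median 0.0303, adjusted p = 0.0189) and from day 7 to day 28 (median 0.0662, adjusted p = 0.0187). For both later calls it was adjusted p = 0.134 with an estimated correlation.

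Of 3866 features called from day 7 to day 14 and from day 14 to day 21, 3511 moved opposite ways. Noise of day 14 RNA, if both comparisons shared it, would give such a pattern, but the covariance of the comparisons was 6.94 times the variance of a single sample estimated from replicates G and F of day 14. The array of G against F was of another print lot than the time arrays. The correlation of the comparisons was -0.492 after the running median was subtracted, from -0.563 before. Both hold day 14, with opposite sign. Levels that vary independently among days 7, 14 and 21 would thus give a negative correlation by arithmetic, with or without a trend. The value therefore cannot decide on a trend along the row order. The opposite moves need both comparisons to run in 1 direction. The loop correlation was 0.713 as read, and -0.0124 or 0.312 with 1 of these 2 comparisons turned. A candidate explanation is a state of adaxial tissue at day 14 that differs from days 7 and 21, but the opposite moves alone do not call for one. Whether the arrays of these comparisons share RNA is not given in the sources used here, so a peculiarity of the day 14 material stays open.

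After the running median was subtracted, day 7 replicates with opposite channel order correlated at 0.0108 and -0.0542 and those with the same order at 0.271. At day 14 the values were -0.0235 and -0.230 for opposite order and 0.346 for the same order. At day 21 they were 0.410 and 0.517 for opposite order and 0.713 for the same order. Between families, the change in adaxial tissue correlated with the change of the side ratio at -0.195 from day 7 to 14, 0.357 from 14 to 21, 0.260 from 21 to 28 and -0.0322 from 7 to 28.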
